A study of Homo sapiens with 94 samples.

How the data were processed

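Primary human synovial fibroblasts of 3 lines were grown in serum-containing medium, treated for 4 or 22 h and lysed, and Smart-seq2 libraries, which cover full-length cDNA without molecular identifiers, were sequenced as paired-end reads, per the labels. The authors deposited a table of estimated counts per Ensembl gene, whose values were not normalized. The submitters' processing notes name kallisto 0.42.4, DESeq2 and the build GRCh38. The annotation release was not given in the sources used here. The table held 58394 genes, of which 58274 had IDs in GENCODE 29, which gave gene positions. The pseudoalignment of short reads splits counts among near-identical genes, so values of paralogs such as the metallothioneins are uncertain, and the library kit does not mark strand. 2 columns with no sample in the labels were not used.

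Groups, lines and culture numbers were taken from the labels. Library totals ran from 3048818 to 5504232 counts. The 46 pairs of cultures differed by more than counting noise, with a chi-square per degree of freedom from 1.66 to 24.7 (median 3.59), and 0 were identical. Counts, which were whole numbers as deposited, were summed over the cultures of a line, treatment and time. Cultures of one line are not independent donors, and summing gave 48 sums. With edgeR 4.0.16 in R 4.3.3, TMM scaling and the default low-count filter, 16985 genes were fitted with a term for each group and for line within time (28 residual degrees of freedom, common biological coefficient of variation 0.126). The two-sided quasi-likelihood tests were adjusted by Benjamini and Hochberg over genes, with a threshold of 0.05. The p values weigh each change against how far treatment responses varied between the 3 lines, with each line's own level taken out. That spread was estimated over all 48 sums together. Lines pair the samples: deviations from group means correlated from 0.329 to 0.623 (median 0.461) between groups for the same line in all 168 pairs.

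Comparisons, gene lists, panel and alternatives were fixed before the data were examined. The 24 lists covered glucocorticoid receptor targets, metallothioneins, NF-kB feedback and target genes, cytokines and chemokines, interferon-stimulated genes, matrix-degrading enzymes, TGF-beta targets, collagens, contractile genes, lining and sublining markers, complement, lipid handling, cholesterol synthesis, proliferation, hypoxia, unfolded protein and amino acid stress, oxidative stress and immediate early genes, and markers of adipocytes, macrophages, endothelial cells, lymphocytes and pericytes. Lists with at least 5 tested members (23) were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated one, adjusted over lists and comparisons. Genes were named for each of the first 7 comparisons by rule: the 5 with the highest and the 5 with the lowest log2 fold change among those past the threshold with an average log2 CPM of at least 3 and one direction in all 3 lines, leaving out genes without an approved-style symbol and Y-linked genes, XIST and TSIX, 3 members of each list past its threshold, a fixed panel of 4 genes, and NR3C1. For the other comparisons genes were named after the values were seen. 1 gene of the panel is not reported here. Where a group had 0 counts, a fold is a lower bound against 3 counts over the group, which covers counting error only. With such members at their bound, 4 of 322 list medians moved by over 0.01, none of them among those given in the text.

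Alternatives were RLE scaling, no low-count filter, no line term, libraries as replicates with line within time as a block or with a block for each line, time and culture number, each time fitted alone, DESeq2 1.42.0, each line left out and each culture number left out. Added after seeing the data were fits without culture pairs with a chi-square per degree of freedom above 10, and with the GC or length trend of each sum removed. The edgeR step was tested on data simulated from the fitted model for FCM against basal medium at 4 h over 16985 genes. Of the genes changed 1.5-fold 40.3%, of those changed 2-fold 73.1% and of those changed 4-fold 86.4% were called. Of all calls 2.21% were false. The changed genes (67, 67 and 66) were picked from those with higher counts, and errors from effects outside the model could not appear. GC trends were checked over 6101 genes, and no library stood apart (slopes from -0.161 to 0.165).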

Results

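Synovial fibroblasts, the stromal cells of the joint lining, were grown from 3 donor lines and profiled by bulk full-length RNA sequencing after 4 or 22 h of treatment. The 8 treatments were medium alone (basal), 100 nM cortisol, fat conditioned medium (FCM), FCM with 10 µM mifepristone, 5 ng/mL TNF, FCM with TNF, 10 ng/mL TGFB, and FCM with TGFB. Cortisol is the natural glucocorticoid, and mifepristone blocks the glucocorticoid and progesterone receptors. TNF is an inflammatory cytokine, and TGFB drives matrix production. Each line had 2 cultures per condition, which gave 94 libraries in 16 groups of 6, except for 4 libraries of FCM with mifepristone at 4 h. There, lines 1 and 2 had a single culture each. Library totals ran from 3048818 to 5504232 estimated counts (median 4257062), and 13216 to 15392 genes per library reached 1 CPM, a count scaled to a common library size. The 2 mitochondrial ribosomal RNAs took 4.81 to 11.8% of the counts. Cultures of one line were summed, so each value below rests on n = 3 lines: levels are mean CPM ± SD, and changes are log2 fold changes ± SE with edgeR quasi-likelihood adjusted p values over 16985 genes. Each SE is the size of the log2 fold change divided by the square root of the test's F value. It is thus an approximation and not an error fitted by the model. Gene lists were fixed before the data were examined and tested with camera.

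Positions of the genes followed most closely were taken from GENCODE 29, in GRCh38 coordinates, and all are annotated as protein-coding with counts given per gene. They were FKBP5 (ENSG00000096060) on chromosome 6 from 35573585 to 35728583, TSC22D3 (ENSG00000157514) on chromosome X from 107713221 to 107777342 and PER1 (ENSG00000179094) on chromosome 17 from 8140472 to 8156506. The others were ZBTB16 (ENSG00000109906) on chromosome 11 from 114059593 to 114250676, NR3C1 (ENSG00000113580) on chromosome 5 from 143277931 to 143435512 and CXCL8 (ENSG00000169429) on chromosome 4 from 73740506 to 73743716, with IL6 (ENSG00000136244) on chromosome 7 from 22725884 to 22732002 and ACTA2 (ENSG00000107796) on chromosome 10 from 88935074 to 88991339.

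**Figure D1:**
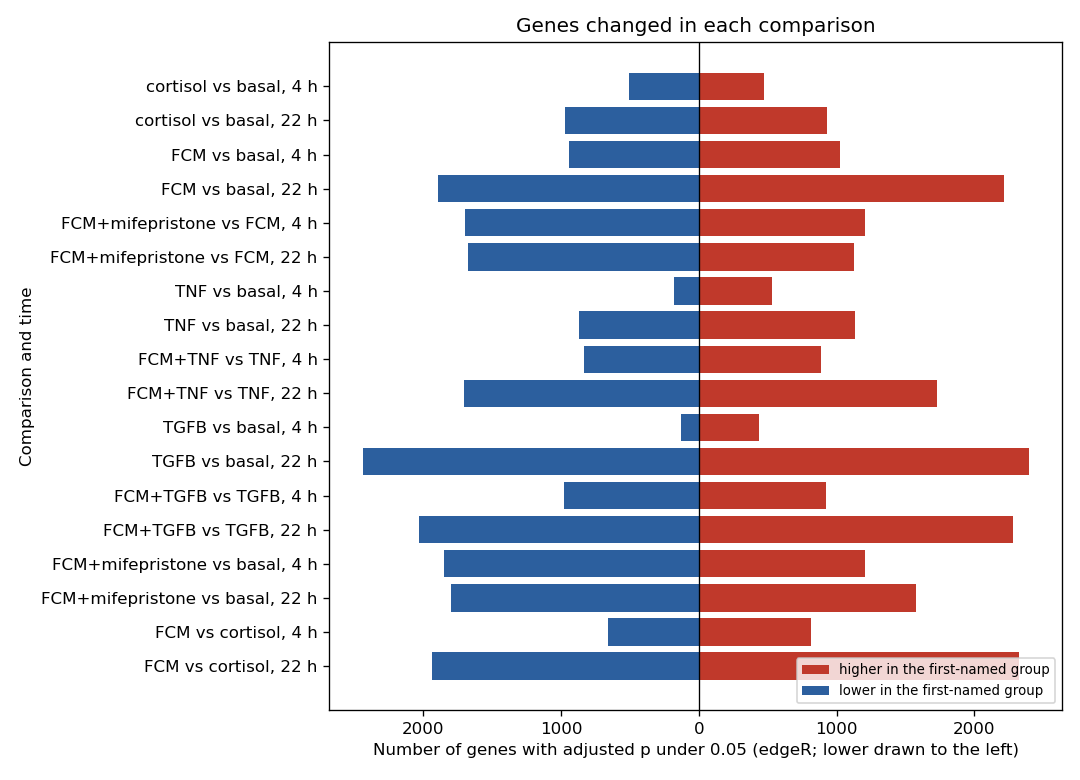
Horizontal bars give the number of genes that were higher (right) or lower (left) in the first-named group of each comparison, at 4 and 22 h, with an edgeR adjusted p under 0.05. The comparison of TGFB with basal ran from 563 genes at 4 h to 4835 at 22 h.

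Cortisol was compared with basal medium to show the response of these fibroblasts to a pure glucocorticoid. FKBP5, a co-chaperone that damps glucocorticoid receptor signalling, rose by 4.58 ± 0.24 at 4 h (137 ± 29.2 against 5.93 ± 1.77 CPM, edgeR adjusted p = 7.49e-16) and by 4.98 ± 0.25 at 22 h. TSC22D3, which encodes the anti-inflammatory protein GILZ, rose by 3.02 ± 0.25 and 3.03 ± 0.24, and the clock gene PER1 by 2.52 ± 0.27 and 1.57 ± 0.26. ZBTB16, with only 3 counts over the basal 4 h cultures, went to 24.4 ± 21.7 against 0.102 ± 0.00987 CPM. NR3C1, the glucocorticoid receptor itself, fell to 50.4 ± 10.7 against 109.7 ± 5.32 CPM at 4 h (-1.14 ± 0.18) and changed by -0.86 ± 0.18 at 22 h.

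Of the glucocorticoid receptor targets, 11 of 26 rose and 1 fell (13 and 1 adjusted over the list alone) at 4 h and 17 of 26 rose and 2 fell (18 and 2 adjusted over the list alone) at 22 h. Metallothioneins, small metal-binding proteins, rose in 5 of 7 members at 4 h and 5 at 22 h (5 and 6 adjusted over the list alone), among them MT1X (2.73 ± 0.17 and 3.27 ± 0.19). Inflammatory cytokines and chemokines moved the other way at 4 h, where 0 of 24 rose and 12 fell (0 and 12 adjusted over the list alone). IL1B fell to 2.26 ± 1.47 against 38.4 ± 7.08 CPM and CXCL2 to 6.12 ± 2.67 against 23.5 ± 6.87 CPM, while IL6 lay at 4.35 ± 2.69 against 47.0 ± 33.1 CPM at 22 h (-3.35 ± 0.56). At 22 h 1 of 24 rose and 6 fell (1 and 8 adjusted over the list alone), with adjusted p = 0.284 with an estimated correlation. Among NF-kB feedback and target genes 0 of 24 rose and 9 fell (0 and 12 adjusted over the list alone) at 4 h, IER3 by -1.67 ± 0.27. This list had adjusted p = 0.168 with an estimated correlation. The synovial lining markers HBEGF (-2.02 ± 0.23) and HAS2 (-2.35 ± 0.33), the latter a hyaluronan synthase, fell, and in that list 0 of 12 rose and 3 fell (0 and 3 adjusted over the list alone). Of the adipocyte markers, 4 of 7 rose and 0 fell (4 and 0 adjusted over the list alone) at 22 h, with LEP, the hormone leptin, at 24.1 ± 13.8 against 0.426 ± 0.226 CPM.

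Later changes included unfolded protein and amino acid stress genes, of which 0 of 22 rose and 10 fell (0 and 11 adjusted over the list alone) at 22 h, among them TRIB3 (-1.71 ± 0.25). That list had adjusted p = 0.0626 with an estimated correlation. TGF-beta target genes fell in 8 of 27 and rose in 2 at 22 h (8 and 3 adjusted over the list alone), and TIMP3, an inhibitor of matrix-degrading enzymes, changed by -2.06 ± 0.25. SAA1, an acute-phase protein, rose to 55.2 ± 45.9 against 0.547 ± 0.743 CPM. The proliferation genes had a median of 0.02 at 22 h, and the list did not pass (adjusted p = 0.893). In all, 977 genes passed at 4 h (472 higher, 505 lower) and 1902 at 22 h (933 higher, 969 lower). Without the line term, 221 genes passed at 4 h and 365 at 22 h. Counts with samples left out were 623 without line 1, 321 without line 2 and 486 without the first cultures at 4 h, and 1110 without line 1, 751 without line 2 and 944 without the first cultures at 22 h. With libraries not summed the 4 h count was 1576 (1525 with a block by culture number). Among the genes named here, the call was lost without the line term for TRIB3 at 22 h.

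FCM was compared with basal medium to show what factors released by fat do to these cells. The same glucocorticoid-responsive genes were measured: FKBP5 rose by 4.19 ± 0.24 at 4 h (112 ± 46.2 against 5.93 ± 1.77 CPM, edgeR adjusted p = 3.40e-15) and 4.03 ± 0.25 at 22 h. PER1 rose by 3.21 ± 0.26 and 1.33 ± 0.26, whereas TSC22D3 rose by 2.87 ± 0.25 at 4 h and stood at 136 ± 35.7 against 91.9 ± 30.2 CPM at 22 h, where it did not pass (adjusted p = 0.0589, higher in 2 of 3 lines). CSF3, the granulocyte growth factor, went from 1 count over the basal cultures at 22 h to 59.9 ± 17.0 against 0.0413 ± 0.0715 CPM. RHCG, an ammonium transporter with 0 counts in basal medium at 22 h, was at least 113-fold higher with FCM, taking a floor of 3 counts over the group. PDK4, a kinase that holds back glucose oxidation, rose by 7.26 ± 0.61, and NR3C1 fell by 1.58 ± 0.19 at 22 h.

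In the glucocorticoid receptor target list 18 of 26 rose and 0 fell (19 and 0 adjusted over the list alone) at 4 h and 18 of 26 rose and 0 fell (21 and 1 adjusted over the list alone) at 22 h, and all 7 metallothioneins rose at both times (7 and 7 adjusted over the list alone). Inflammatory cytokines and chemokines rose at 22 h: 14 of 24 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 1.64 and adjusted p = 5.70e-14, and adjusted p = 0.0381 with an estimated correlation. The neutrophil-attracting chemokines CXCL3 (125 ± 41.9 against 2.62 ± 0.157 CPM) and CXCL6 (352 ± 246 against 8.82 ± 7.45 CPM) were among them. At 4 h 8 of 24 rose and 5 fell (11 and 6 adjusted over the list alone), with adjusted p = 0.604 with an estimated correlation. Contractile genes fell at 22 h in 14 of 16 members (15 adjusted over the list alone), among them ACTA2, smooth muscle actin (56.4 ± 19.1 against 348 ± 259 CPM, -2.29 ± 0.27). Of the collagens and matrix proteins 2 of 30 rose and 15 fell (3 and 17 adjusted over the list alone), with COL1A1 at -1.14 ± 0.13 and adjusted p = 0.146 for the list with an estimated correlation.

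Proliferation genes rose at 22 h in 22 of 26 members (25 adjusted over the list alone), such as the replication helicase subunit MCM3 (1.38 ± 0.16), with adjusted p = 0.173 with an estimated correlation. Unfolded protein and amino acid stress genes fell in 15 of 22 and rose in 1 (16 and 2 adjusted over the list alone), with DDIT3, a stress transcription factor, at 10.3 ± 0.883 against 80.7 ± 10.7 CPM. Immediate early genes rose in 11 of 22 and fell in 3 (14 and 4 adjusted over the list alone), including EGR1 (1.88 ± 0.26). For lipid handling genes 8 of 19 rose and 1 fell (9 and 1 adjusted over the list alone), ANGPTL4, an inhibitor of lipoprotein lipase, by 3.64 ± 0.19. The lists of markers of other cell types were given the same test: of 7 macrophage markers 3 rose and 1 fell (adjusted p = 0.394). Of 5 endothelial markers 2 rose and 1 fell (adjusted p = 0.778). Finally, 4 of 7 adipocyte markers rose, as many as with cortisol at 22 h (camera adjusted p = 0.0506 with an estimated correlation). The macrophage and endothelial p values are with the preset correlation, so they do not compare directly with it. FCM changed 1970 genes at 4 h (1027 higher, 943 lower) and 4111 at 22 h (2215 higher, 1896 lower). A fit with no line term called 747 and 1752 genes at 4 and 22 h. Fits with fewer samples gave 1224 without line 1, 1115 without line 2 and 1159 without the first cultures at 4 h, and 2667 without line 1, 2620 without line 2 and 2428 without the first cultures at 22 h. The call was lost without the line term for COL1A1 at 22 h.

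**Figure D2:**
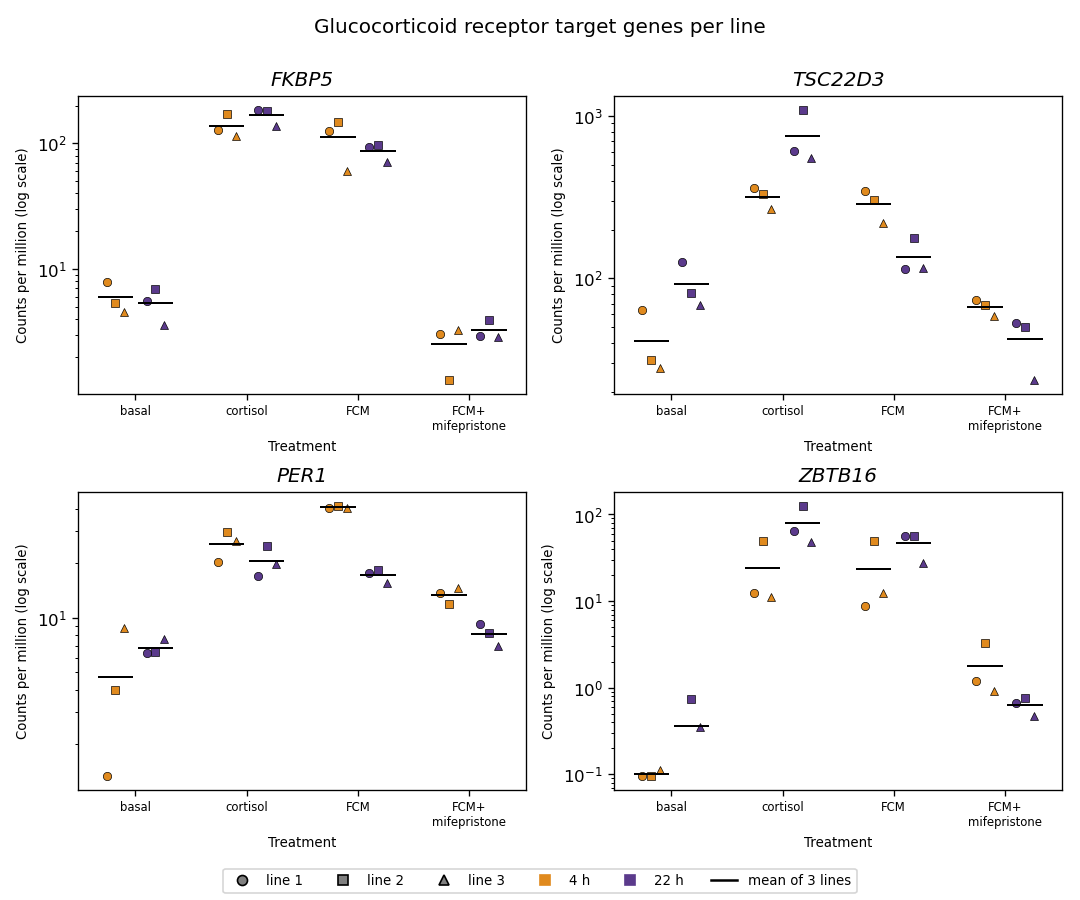
Points give CPM on a log axis for FKBP5, TSC22D3, PER1 and ZBTB16 in each of the 3 lines (circle, square, triangle) at 4 h (orange) and 22 h (purple), and bars mark the mean. FKBP5 lay near 5.93 CPM in basal medium at 4 h, 137 with cortisol, 112 with FCM and 2.52 with FCM and mifepristone. A ZBTB16 value of 0 in 1 basal 22 h line is not drawn.

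The responses to cortisol and to FCM shared 290 risen and 227 fallen genes at 4 h, where independent lists would share 28.5 and 28.0, and 377 and 434 at 22 h (122 and 108 for independent lists). Across genes, which are not independent replicates, the correlation was 0.555 at 4 h and 0.439 at 22 h, against 0.489 and 0.515 for simulated unchanged groups sharing the basal cultures. With the basal cultures split between the comparisons it was 0.318 and 0.266, and the covariance exceeded the simulated one by 0.159 and 0.146. FCM and cortisol were also compared directly, with the lists counted but not tested by camera. FCM differed in 1473 genes at 4 h and 4258 at 22 h. CXCL6 (352 ± 246 against 2.27 ± 1.29 CPM) and CXCL5 (6.72 ± 0.56), both chemokines, were higher with FCM at 22 h, as were 18 of 24 cytokines and chemokines (18 adjusted over the list alone). ANGPTL7 (3.47 ± 4.37 against 83.1 ± 86.8 CPM) and ACTC1, cardiac actin (-4.87 ± 0.36), were lower. The counts with no line term were 291 at 4 h and 1688 at 22 h. Leaving out lines or cultures gave 750 without line 1, 790 without line 2, 715 without line 3 and 663 without the first cultures at 4 h, and 2166 without line 2 at 22 h. At 4 h the count was 877 without the culture pairs that differed most, and 2325 with libraries not summed (2221 with a block by culture number).

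Mifepristone was added to FCM to ask which part of the FCM response runs through the glucocorticoid receptor. FKBP5 fell with it by 5.25 ± 0.29 at 4 h (2.52 ± 1.07 against 112 ± 46.2 CPM, edgeR adjusted p = 3.17e-15) and by 4.73 ± 0.26 at 22 h, to 3.25 CPM. ZBTB16 changed by -3.65 ± 0.38 and -6.16 ± 0.36, TSC22D3 by -2.09 ± 0.24 and -1.75 ± 0.24, and PER1 by -1.62 ± 0.24 and -1.08 ± 0.25. The prostaglandin synthase PTGS2 rose by 3.22 ± 0.55 at 4 h, TSLP, an alarmin cytokine, by 3.35 ± 0.52, and NR3C1 by 0.93 ± 0.18. Of the glucocorticoid receptor targets, 1 of 26 rose and 18 fell (1 and 20 adjusted over the list alone) at 4 h and 2 of 26 rose and 19 fell (2 and 20 adjusted over the list alone) at 22 h. Metallothioneins fell in 6 of 7 members at each time (7 and 6 lower, 0 and 1 higher adjusted over the list alone), with medians of -1.44 and -1.27 and adjusted p = 1.58e-10 and 8.52e-09.

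All 26 proliferation genes fell at 22 h (26 adjusted over the list alone; median -1.73, adjusted p = 1.89e-44, and adjusted p = 0.00379 with an estimated correlation). MKI67, a marker of dividing cells, stood at 9.67 ± 2.92 against 44.9 ± 8.87 CPM, and the cyclin CCNB1 changed by -1.64 ± 0.17. Cytokines and chemokines rose at 4 h in 14 of 24 members (14 adjusted over the list alone), CXCL6 by 2.68 ± 0.35, with adjusted p = 0.103 with an estimated correlation. Stress genes of the amino acid and unfolded protein responses rose at 22 h in 14 of 22 (15 adjusted over the list alone), such as the asparagine synthetase gene ASNS (1.94 ± 0.20). Matrix-degrading enzymes rose in 8 of 17 at 22 h (12 adjusted over the list alone), the collagenase MMP1 to 138 ± 83.7 against 22.9 ± 12.7 CPM, and hypoxia and glycolysis genes in 13 of 26 with 2 lower (16 and 2 adjusted over the list alone). Collagens and matrix proteins fell at 4 h in 16 of 30 (18 adjusted over the list alone, camera adjusted p = 0.0595 with an estimated correlation). Of the cholesterol and fatty acid synthesis genes 8 of 27 fell at 22 h (8 adjusted over the list alone, camera adjusted p = 0.328 with an estimated correlation).

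Mifepristone changed 2903 genes at 4 h (1204 higher, 1699 lower) and 2806 at 22 h (1127 higher, 1679 lower). At 4 h lines 1 and 2 had a single culture with mifepristone, and the fit gave these sums the spread shared by all groups. Fitted on the compared groups alone, the counts were 1489 at 4 h and 3207 at 22 h. Genes that rose with cortisol and fell with mifepristone numbered 295 at 4 h and 338 at 22 h, against 47.2 and 92.2 for independent lists, in comparisons that share no library. Between FCM and mifepristone, which share the FCM cultures, 457 and 902 genes rose and then fell (375 and 658 with the shared cultures split), and the correlation at 22 h was -0.487, against -0.510 for simulated unchanged groups. With the shared cultures split it was -0.270, and the covariance of -0.290 lay below the simulated -0.111, a difference of -0.180. Leaving the line term out gave 993 genes at 4 h and 697 at 22 h. Counts with samples left out were 794 without line 1, 702 without line 2, 147 without the first cultures and 1593 without the second cultures at 4 h, and 1521 without line 1 and 1350 without line 2 at 22 h. Calls that did not hold were those without the line term for PER1 at 22 h, TSLP at 4 h, ASNS at 22 h and MMP1 at 22 h, and without line 2 for PER1 at 22 h, and without the first cultures for NR3C1 at 4 h and CXCL6 at 4 h. Leaving out the first cultures at 4 h removed all but 1 of the mifepristone sums, whose spread was assumed to be that of the other groups.

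Set against basal medium, the receptor targets with FCM and mifepristone went different ways. At 4 h PER1 (13.4 ± 1.36 against 4.71 ± 3.80 CPM, 1.59 ± 0.29, edgeR adjusted p = 1.45e-04) and TSC22D3 (67.0 ± 7.45 against 41.2 ± 19.7 CPM, adjusted p = 0.0230) were higher, as was ZBTB16 (1.79 ± 1.27 against 0.102 ± 0.00987 CPM, adjusted p = 0.00153), which had 3 counts over the basal cultures. FKBP5 was lower at 4 h (-1.06 ± 0.37, adjusted p = 0.0418). At 22 h TSC22D3 was lower (-1.15 ± 0.24), and FKBP5 (adjusted p = 0.144), PER1 (adjusted p = 0.615) and ZBTB16 (adjusted p = 0.548) did not pass. Without the line term the calls were lost for TSC22D3 at both times and for FKBP5 and ZBTB16 at 4 h, and without the first cultures for all 4 genes at 4 h. The 4 h calls were lost without line 2 and without the second cultures for FKBP5 and TSC22D3, without line 1 for FKBP5 and without line 3 for TSC22D3. That of FKBP5 was lost too with each time fitted alone and with the GC or length trend removed. Its 22 h difference passed with no filter on low counts, with each time fitted alone and without the first cultures.

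Against basal medium, FCM with mifepristone still raised CSF3 (209 ± 128 against 3.82 ± 5.62 CPM at 4 h) and at 22 h CXCL8 (743 ± 238 against 14.7 ± 13.2 CPM) and CXCL6 (6.30 ± 0.43). Of the cytokines and chemokines, 14 of 24 rose and 1 fell (16 and 1 adjusted over the list alone) at 22 h, and 7 of 7 metallothioneins rose (7 adjusted over the list alone). Proliferation genes were lower than in basal medium in 16 of 26 cases and higher in 2 (16 and 2 adjusted over the list alone). CCN2, a matrix-associated growth regulator, fell to 121 ± 52.0 against 2300 ± 1039 CPM, and contractile genes fell in 14 of 16 (14 adjusted over the list alone). With edgeR 3059 genes passed at 4 h and 3373 at 22 h. Fitted on the compared groups alone, 1247 and 2754 genes passed. Without the line term, 1087 genes passed at 4 h and 1214 at 22 h. Fits with fewer samples gave 953 without line 1, 1292 without line 2, 232 without the first cultures and 1839 without the second cultures at 4 h, and 1883 without line 1, 1960 without line 2 and 2247 without the second cultures at 22 h.

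**Figure D3:**
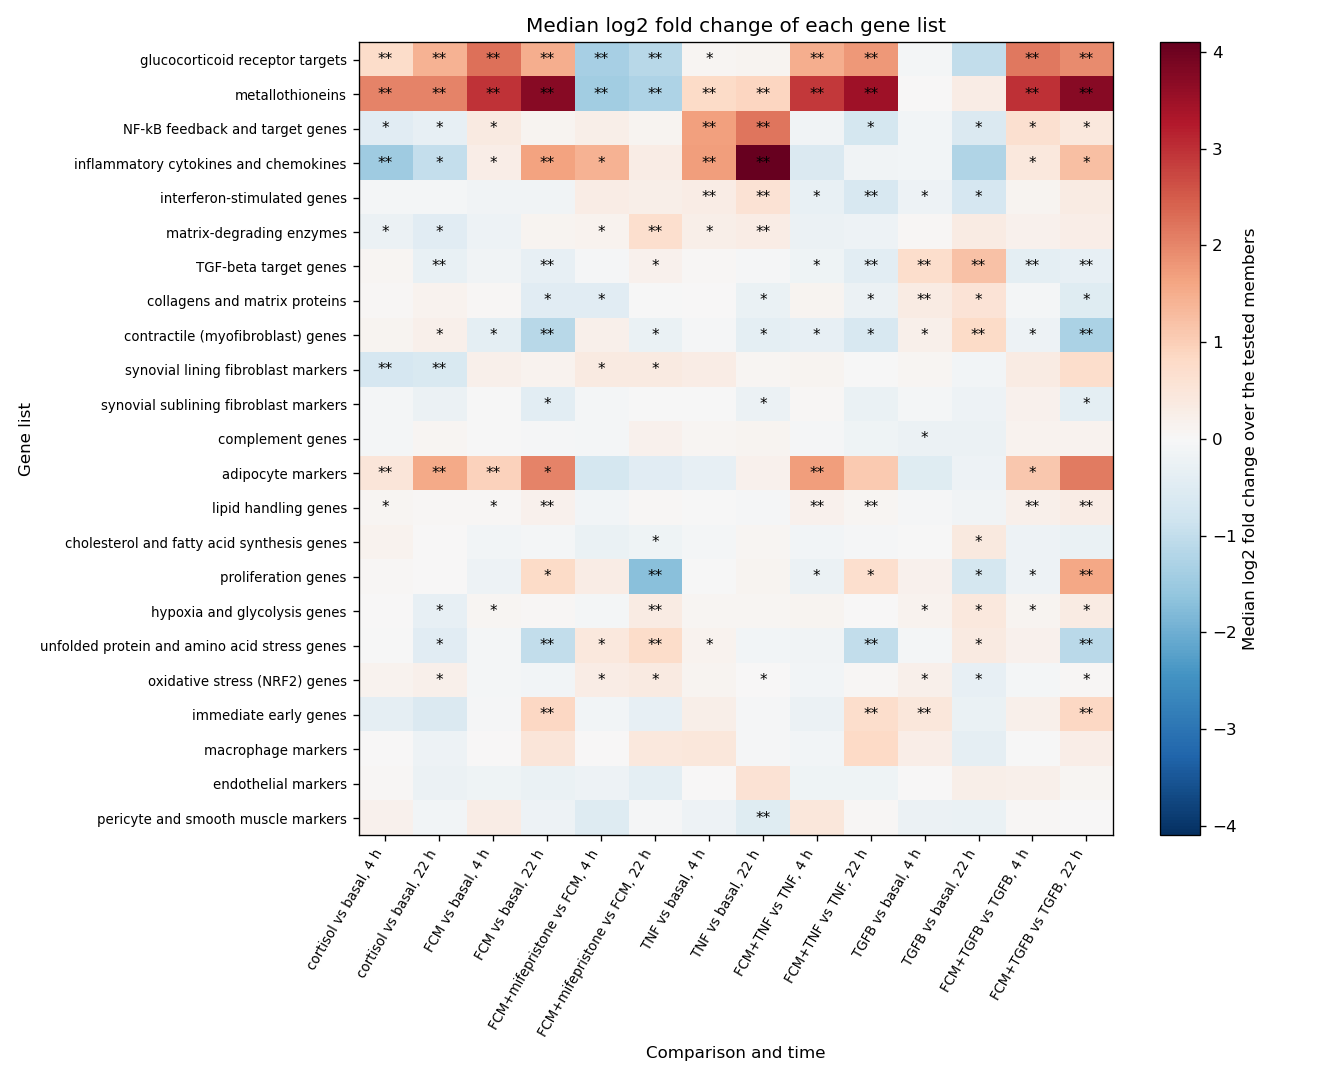
Colour gives the median log2 fold change of the tested members of each gene list (vertical axis) in each comparison and time (horizontal axis). A single star marks a camera adjusted p under 0.05 with the preset correlation, and a double star one that also holds with an estimated correlation. The highest median was 4.09, for inflammatory cytokines and chemokines with TNF at 22 h.

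TNF was compared with basal medium as an inflammatory stimulus. CXCL8, the neutrophil attractant interleukin-8, rose by 3.06 ± 0.41 at 4 h and 7.01 ± 0.51 at 22 h (1714 ± 681 against 14.7 ± 13.2 CPM, edgeR adjusted p = 2.51e-12). IL6 rose by 1.53 ± 0.42 and 2.86 ± 0.45. The monocyte attractant CCL2 rose by 1.48 ± 0.42 and 3.22 ± 0.46, and the stromelysin MMP3 by 3.08 ± 0.49 and 3.32 ± 0.51. In the list of NF-kB feedback and target genes 23 of 24 rose and 0 fell (23 and 0 adjusted over the list alone) at 4 h and 22 of 24 rose and 0 fell (23 and 0 adjusted over the list alone) at 22 h, with TNFAIP3, an inhibitor of the pathway, at 349 ± 26.8 against 30.5 ± 8.23 CPM. Cytokines and chemokines rose in 18 of 24 at 4 h and 21 at 22 h (20 and 24 adjusted over the list alone). Interferon-stimulated genes rose in 6 of 27 and 13 (8 and 18 adjusted over the list alone), the antiviral gene MX1 by 2.49 ± 0.34.

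Matrix-degrading enzymes rose at 22 h in 6 of 17 members (6 adjusted over the list alone), MMP1 by 3.98 ± 0.41. In the sublining marker list 1 of 17 rose and 6 fell (1 and 7 adjusted over the list alone) at 22 h, PDGFRB, a growth factor receptor, by -1.32 ± 0.17, with adjusted p = 0.227 with an estimated correlation. Contractile genes fell in 7 of 16 (8 adjusted over the list alone; adjusted p = 0.167 with an estimated correlation). Of 13 complement genes 2 rose and 0 fell at 22 h (adjusted p = 0.102), and of 9 pericyte and smooth muscle markers 1 fell, NOTCH3 (-1.56 ± 0.33; 3 adjusted over the list alone). TNF changed 710 genes at 4 h (533 higher, 177 lower) and 2008 at 22 h (1136 higher, 872 lower). A fit with no line term called 172 and 501 genes at 4 and 22 h. Leaving out lines or cultures gave 258 without line 1, 275 without line 2 and 417 without the second cultures at 4 h, and 1263 without line 1, 794 without line 2 and 1287 without the first cultures at 22 h. Unsummed libraries gave 1264 genes at 4 h (1207 with a block by culture number). Of the named genes, calls ended without the line term for CXCL8 at 4 h, IL6 at 4 h, CCL2 at 4 h, MMP3 at 4 h, MMP1 at 22 h and NOTCH3 at 22 h, and without line 1 and without the second cultures for IL6 at 4 h and CCL2 at 4 h, and without line 2 for IL6 at 4 h, CCL2 at 4 h and NOTCH3 at 22 h.

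FCM with TNF was compared with TNF alone to show how FCM alters an inflamed state. VCAM1, an adhesion molecule for leukocytes, stood at 15.9 ± 17.1 against 389 ± 88.4 CPM at 22 h (-5.11 ± 0.46, edgeR adjusted p = 1.18e-10), and ICAM1, another, changed by -2.21 ± 0.27. VCAM1 was also lower with FCM in the absence of TNF, at 33.77, 6.249 and 6.226 CPM in lines 1, 2 and 3 at 22 h. Its levels in these lines were 280.7, 86.32 and 80.56 CPM in basal medium and 35.71, 6.658 and 5.435 CPM with FCM and TNF. CCL2 and MMP3 fell at 4 h (-1.82 ± 0.43 and -1.90 ± 0.46). At 22 h CCL2 (-0.81 ± 0.42, adjusted p = 0.184), MMP3 (-0.20 ± 0.45, adjusted p = 0.826), IL6 (0.49 ± 0.41, adjusted p = 0.469) and CXCL8 (-0.20 ± 0.38, adjusted p = 0.789) did not pass the edgeR test. CSF3 rose to 231 ± 60.6 against 1.23 ± 0.838 CPM. Cytokines and chemokines divided: 5 of 24 rose and 11 fell (6 and 12 adjusted over the list alone) at 4 h and 8 of 24 rose and 8 fell (9 and 8 adjusted over the list alone) at 22 h, and the camera test did not pass at either time (adjusted p = 0.0596 and 0.358).

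Of the NF-kB feedback and target genes 3 of 24 rose and 12 fell (3 and 14 adjusted over the list alone) at 22 h, with adjusted p = 0.365 with an estimated correlation. Interferon-stimulated genes fell in 14 of 27 and rose in 1 (18 and 1 adjusted over the list alone), with MX1 at -2.41 ± 0.33. Glucocorticoid receptor targets rose in 17 of 26 at 4 h and 18 at 22 h (18 and 19 adjusted over the list alone), FKBP5 by 4.45 ± 0.25 and 4.36 ± 0.26. Stress genes fell in 18 of 22 at 22 h (18 adjusted over the list alone), CHAC1, a glutathione-degrading enzyme, by 3.26 ± 0.25. FCM changed 1721 genes under TNF at 4 h (889 higher, 832 lower) and 3432 at 22 h (1727 higher, 1705 lower). The FCM responses without and with TNF, which share no library, had 1238 risen and 995 fallen genes in common at 22 h, against 225 and 190.3 for independent lists, and a correlation across genes of 0.591 (0.160 with no filter on low counts). The counts with no line term were 558 at 4 h and 1269 at 22 h. Counts with samples left out were 999 without line 1, 808 without line 2 and 995 without the second cultures at 4 h, and 1939 without line 2 at 22 h. Unsummed libraries gave 2588 genes at 4 h. A call failed without the line term and without line 1 for MMP3 at 4 h.

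TGFB was compared with basal medium as a matrix-inducing stimulus. PMEPA1, a feedback inhibitor of the TGF-beta pathway, rose by 2.16 ± 0.21 at 4 h and 3.74 ± 0.23 at 22 h. ACTA2 was unresolved at 4 h (0.14 ± 0.25, adjusted p = 0.872) and rose by 2.53 ± 0.26 at 22 h (1997 ± 1481 against 348 ± 259 CPM, edgeR adjusted p = 1.83e-09). COL1A1 rose by 0.46 ± 0.13 at 4 h and missed the threshold at 22 h (0.23 ± 0.13, adjusted p = 0.220). TGF-beta target genes rose in 14 of 27 at 4 h and 19 at 22 h, with 1 and 4 lower (adjusted over the list alone, 20 and 19 higher). The cell cycle inhibitor CDKN2B went to 196 ± 104 against 10.7 ± 2.33 CPM at 22 h.

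Contractile genes rose at 22 h in 11 of 16 members (12 adjusted over the list alone), CNN1, calponin, by 4.66 ± 0.47. Of the collagens and matrix proteins 16 of 30 rose and 2 fell (17 and 4 adjusted over the list alone) at 22 h, COL4A1 by 2.84 ± 0.19, with adjusted p = 0.101 with an estimated correlation. Proliferation genes fell in 16 of 26 (18 adjusted over the list alone), the thymidylate synthase gene TYMS by 2.32 ± 0.23, with adjusted p = 0.399 with an estimated correlation. NF-kB feedback and target genes fell in 12 of 24 and rose in 1 (13 and 2 adjusted over the list alone; adjusted p = 0.424 with an estimated correlation). Oxidative stress genes fell in 11 of 20 and rose in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.216 with an estimated correlation). TGFB changed 563 genes at 4 h (434 higher, 129 lower) and 4835 at 22 h (2394 higher, 2441 lower). At 22 h mitochondrial ribosomal RNA took 4.81 to 7.54% of the counts in the 6 TGFB libraries and 8.29 to 9.75% in the 6 basal ones, and mitochondrial coding genes took means of 1.25 ± 0.218 and 1.57 ± 0.124%. Genes with a count numbered 20620 ± 778 and 21561 ± 319 per library. Whether TGFB and basal libraries were prepared together is not given in the sources used here, so a batch difference between them was not tested. Leaving the line term out gave 94 genes at 4 h and 2602 at 22 h. Fits with fewer samples gave 258 without line 1, 154 without line 2, 341 without the first cultures and 317 without the second cultures at 4 h. Gene calls were lost without the line term for PMEPA1 at 4 h and COL1A1 at 4 h, and with each time fitted alone, without line 1, without line 2 and without the second cultures for COL1A1 at 4 h. With no filter on low counts the 4 h count was 916, and with libraries not summed 1208 (1135 with a block by culture number).

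FCM with TGFB was compared with TGFB alone to show how FCM alters the matrix-producing state. ACTA2 fell by 4.48 ± 0.29 at 22 h (80.9 ± 44.3 against 1997 ± 1481 CPM, edgeR adjusted p = 1.33e-14), with a mean of 348 CPM in basal medium, and CDKN2B went to 8.71 ± 2.89 against 196 ± 104 CPM. COL1A1 changed by -1.17 ± 0.13 at 22 h, whereas PMEPA1 did not pass (0.17 ± 0.19, adjusted p = 0.579). The rise of COL1A1 with TGFB had missed the threshold at 22 h, and FCM lowered COL1A1 in the absence of TGFB too. At 4 h ACTA2, COL1A1 and PMEPA1 all missed the threshold. CSF3, with 0 counts under TGFB at 22 h, was at least 632-fold higher and CCL20, a chemokine likewise at 0, at least 64.6-fold higher, each against 3 counts over the group. CXCL1 rose by 9.69 ± 0.65 and KRT18, a keratin, fell to 0.472 ± 0.344 against 110.3 ± 89.9 CPM.

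Contractile genes fell at 22 h in 15 of 16 members (15 adjusted over the list alone; adjusted p = 4.19e-24, and adjusted p = 3.12e-04 with an estimated correlation). TGF-beta targets fell in 9 of 27 and rose in 3 (11 and 3 adjusted over the list alone), with TIMP3 at -3.27 ± 0.26. All 26 proliferation genes rose (26 adjusted over the list alone; median 1.59), RRM2, a ribonucleotide reductase subunit, by 2.54 ± 0.26. Cytokines and chemokines rose in 9 of 24 (9 adjusted over the list alone; adjusted p = 0.0626 with an estimated correlation). Glucocorticoid receptor targets rose in 22 of 26 (22 adjusted over the list alone), and stress genes fell in 15 of 22 with 2 higher (16 and 2 adjusted over the list alone). The aldo-keto reductase AKR1C1 rose by 4.94 ± 0.26. FCM changed 1902 genes under TGFB at 4 h (926 higher, 976 lower) and 4314 at 22 h (2280 higher, 2034 lower). At 22 h mitochondrial ribosomal RNA took 7.79 ± 1.17% of the counts in the 6 libraries with FCM and TGFB and 6.33 ± 1.28% in the 6 with TGFB, and mitochondrial coding genes 1.63 ± 0.121 and 1.25 ± 0.218%. The line 3 cultures with FCM and TGFB differed most of all pairs (chi-square per degree of freedom 24.7), and 1 of them stood apart at 5.46%. Without the culture pairs that differed most 3569 genes passed at 22 h. With the FCM response in basal medium, which shares no library, it had 1351 risen and 1110 fallen genes in common at 22 h (297 and 227 for independent lists), with a correlation across genes of 0.597 (0.176 with no filter on low counts). Without the line term, 702 genes passed at 4 h and 2175 at 22 h. Leaving out lines or cultures gave 943 without line 1, 1083 without line 2 and 1158 without the first cultures at 4 h, and 2662 without line 2 at 22 h. Among the genes named here, the call was lost without the line term for COL1A1 at 22 h.

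**Figure D4:**
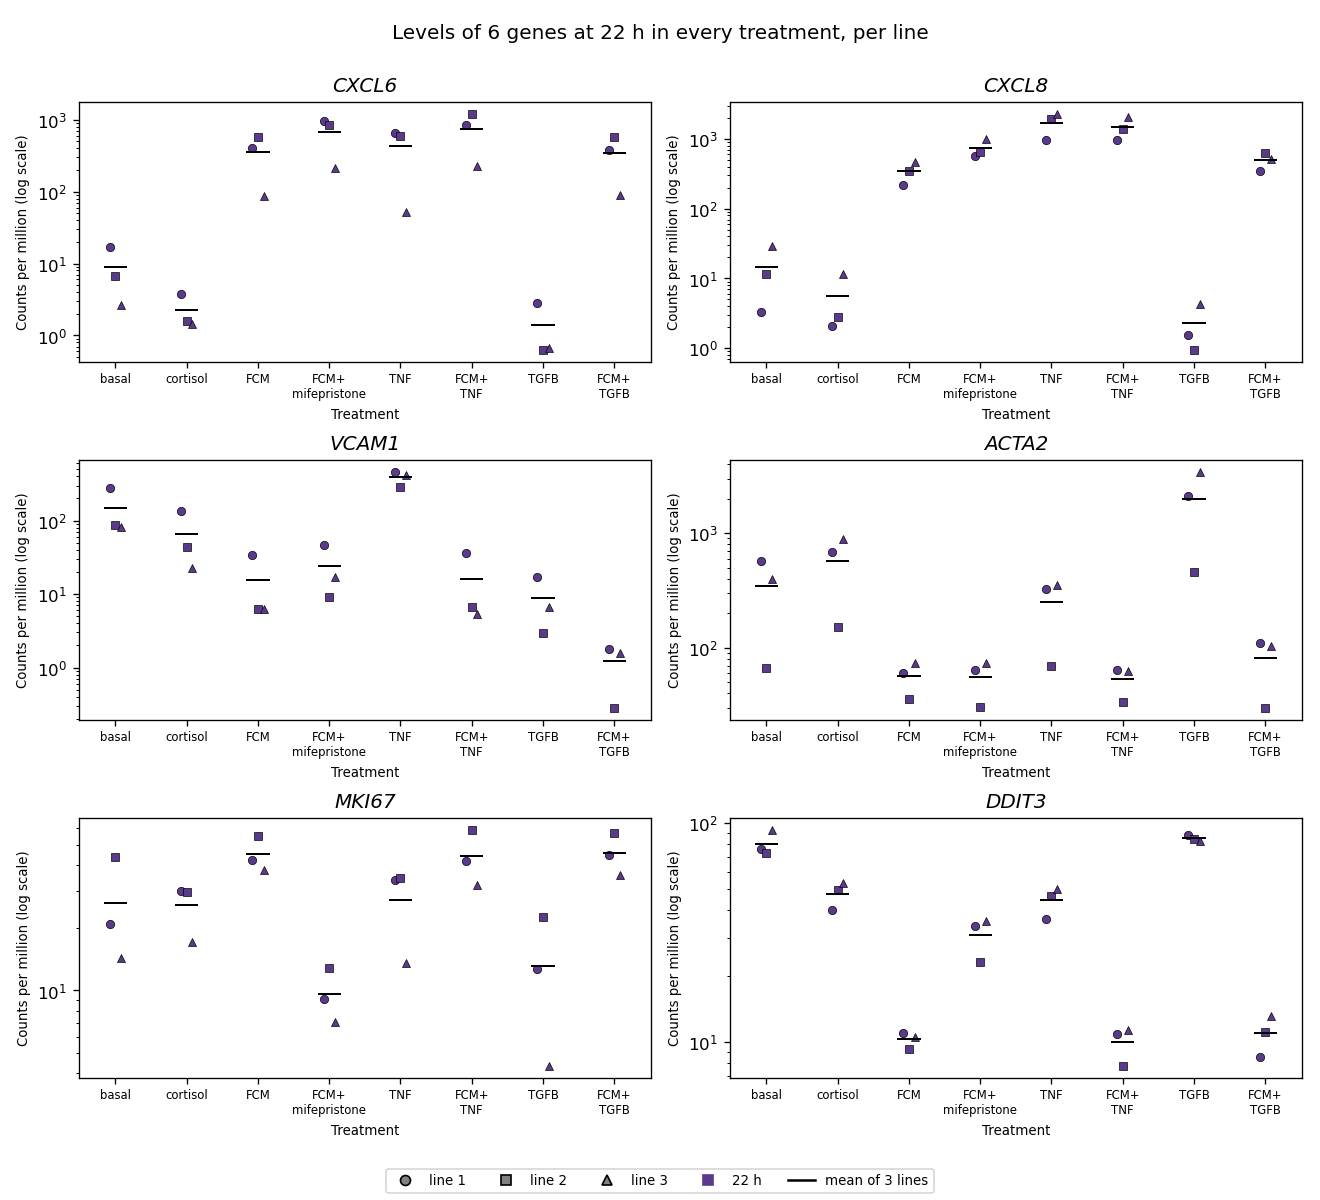
Points give CPM on a log axis at 22 h in each of the 3 lines (circle, square, triangle) for every treatment, and bars mark the mean, for CXCL6, CXCL8, VCAM1, ACTA2, MKI67 and DDIT3. ACTA2 had a mean of 1997 CPM with TGFB and 80.9 with FCM and TGFB, and VCAM1 389 with TNF and 15.9 with FCM and TNF.

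Whether the FCM response differed in the presence of a cytokine was tested as an interaction, with genes named by the same rule applied after the values were seen. For TNF it passed in 6 genes at 4 h and 175 at 22 h. Of the latter, 51 were higher and 124 lower than the sum of both single responses on the log2 scale. That sum multiplies the folds, so a level below it can still exceed that of each single treatment. At 22 h the chemokines CXCL8 (-4.90 ± 0.60), CXCL6 (-4.21 ± 0.51) and CXCL3 (-3.67 ± 0.45) lay below that log2 sum, as did TFPI2, a protease inhibitor (-3.76 ± 0.46). In lines 1, 2 and 3, CXCL6 stood at 836.7, 1190 and 223.5 CPM with FCM and TNF. Its levels were 647.1, 590.4 and 52.43 CPM with TNF and 397, 572.8 and 86.69 with FCM. CXCL8 stood at 972.7, 1405 and 2037 CPM with FCM and TNF and at 955.2, 1918 and 2270 with TNF. In the cytokine and chemokine list 8 of 24 members were lower and 0 higher (14 and 0 adjusted over the list alone). For TGFB it passed in 2 genes at 4 h, MYC (-1.13 ± 0.18) and SPRY4 (-0.93 ± 0.17), and in 349 at 22 h (169 higher, 180 lower), among them CDKN2B (-2.96 ± 0.29) and PTHLH, a parathyroid hormone relative (-4.72 ± 0.58). Without the line term the interaction counts were 0 and 14 for TNF and 0 and 13 for TGFB at 4 and 22 h. With no filter on low counts they were 196 and 525 for TNF and 126 and 713 for TGFB. With libraries not summed they were 67 and 624 for TNF and 46 and 1169 for TGFB (58, 567, 32 and 1080 with a block by culture number). DESeq2 gave 8 and 543 for TGFB. With each time fitted alone the 4 h counts were 2 for TNF and 0 for TGFB, and for TGFB at 4 h 8 genes passed without the culture pairs that differed most and 4 with the GC trend removed. For TNF they were 0 without line 1 and 1 without line 2 at 4 h and 46 without line 1, 23 without line 2, 107 without line 3 and 70 without the first cultures at 22 h. For TGFB they were 0 without line 1, 0 without line 2, 1 without line 3, 0 without the first cultures and 1 without the second cultures at 4 h and 74 without line 1, 67 without line 2 and 169 without line 3 at 22 h. The call was lost without the line term for CXCL8 at 22 h, CXCL6 at 22 h, MYC at 4 h and SPRY4 at 4 h, and with each time fitted alone, without line 1, without line 2, without line 3 and without the first cultures for MYC at 4 h and SPRY4 at 4 h, and without the second cultures for SPRY4 at 4 h.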

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

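The tests of carried-over RNA, of GC content, of mislabelled cultures and of the glucocorticoid receptor's share, and the counts over other splits, were chosen after the results were seen. The interaction and time difference tests were planned. Of 48 group and measure combinations tested for a library apart from the rest, 3 had one, all in the share of counts taken by mitochondrial ribosomal RNA. Chance flags about 1 in 20 groups. The values were 5.46% in a culture of line 3 with FCM and TGFB at 22 h (others 7.84 to 8.64%), 10.8% in a culture of line 1 with TGFB at 4 h (others 7.92 to 8.94%) and 6.84% in a culture of line 3 with cortisol at 4 h (others 10.0 to 11.3%).

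Responses differed between 4 and 22 h in 270 genes for cortisol, 2180 for FCM, 1589 for mifepristone added to FCM, 403 for TNF, 1491 for FCM added to TNF, 2040 for TGFB and 2185 for FCM added to TGFB, by edgeR's test of the difference. For cortisol the count was 58 without line 1, 69 without line 2, 144 without line 3, 114 without the first cultures and 132 without the second cultures. For FCM the count was 1186 without line 1, 868 without line 2, 1306 without line 3 and 929 without the first cultures. For mifepristone the count was 440 without line 1, 172 without line 2 and 37 without the first cultures. For TNF the count was 134 without line 1, 54 without line 2, 255 without line 3, 219 without the first cultures and 246 without the second cultures. For FCM added to TNF the count was 887 without line 1, 462 without line 2, 850 without line 3, 869 without the first cultures and 837 without the second cultures. For TGFB the count was 858 without line 1, 749 without line 2, 1188 without the first cultures and 1259 without the second cultures. For FCM added to TGFB the count was 1263 without line 1, 918 without line 2, 1325 without the first cultures and 1406 without the second cultures. With no filter on low counts the count was 583 for cortisol and 717 for TNF. Libraries not summed gave 701 for cortisol, 1090 for TNF, 2595 for FCM added to TNF and 3146 for TGFB. Among the panel genes, the rise with FCM was smaller at 22 h than at 4 h for TSC22D3 (-2.27 on the log2 scale) and PER1 (-1.89). The fall of ZBTB16 with mifepristone was larger at 22 h (-2.51). The TNF response was higher at 22 h for CXCL8 (3.95), and the TGFB response for ACTA2 (2.39) and PMEPA1 (1.58). In lines 1, 2 and 3 the CXCL8 level with TNF was lower at 22 h (955.2, 1918 and 2270 CPM) than at 4 h (2765, 2352 and 3069). Its basal level was 200.2, 192.8 and 874.8 CPM at 4 h and 3.262, 11.64 and 29.14 at 22 h. With FCM added to TGFB, ACTA2 (-4.38) and COL1A1 (-0.93) fell further at 22 h than at 4 h, where both missed the threshold.

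The interaction of FCM with TNF passed in 6 genes at 4 h and 175 at 22 h, and that with TGFB in 2 and 349. The genes at 4 h for TNF, named after their values were seen, were PRICKLE1 (2.40 ± 0.39), JADE1 (1.24 ± 0.25), SRGAP1 (0.81 ± 0.12), YPEL2 (-2.07 ± 0.41), ALAS1 (-0.90 ± 0.15) and ENSG00000267288 (-3.60 ± 0.69). The counts were 0 without line 1 and 1 without line 2 at 4 h and 46 without line 1, 23 without line 2, 107 without line 3 and 70 without the first cultures at 22 h for TNF. For TGFB they were 0 without line 1, 0 without line 2, 1 without line 3, 0 without the first cultures and 1 without the second cultures at 4 h and 74 without line 1, 67 without line 2 and 169 without line 3 at 22 h. With no filter on low counts they were 196 and 525 for TNF and 126 and 713 for TGFB at 4 and 22 h, and with libraries not summed 67 and 624 for TNF and 46 and 1169 for TGFB.

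Other splits of the 3 lines per group were counted with the line term. The 10 splits of each comparison of a pair of groups, of which 4 part all 3 pairs, are too few for a share under 0.05, as are the 4 of each interaction and time difference. For each comparison of a pair of groups the highest other split gave 0 genes, so 1 split reached the real count. For cortisol vs basal, 4 h the count was 1239, for cortisol vs basal, 22 h 1868 and for FCM vs basal, 4 h 1745. For FCM vs basal, 22 h the count was 3302, for FCM+mifepristone vs FCM, 4 h 1489 and for FCM+mifepristone vs FCM, 22 h 3207. For TNF vs basal, 4 h the count was 1122, for TNF vs basal, 22 h 2070 and for FCM+TNF vs TNF, 4 h 1569. For FCM+TNF vs TNF, 22 h the count was 2542, for TGFB vs basal, 4 h 726 and for TGFB vs basal, 22 h 3777. For FCM+TGFB vs TGFB, 4 h the count was 1055, for FCM+TGFB vs TGFB, 22 h 2881 and for FCM+mifepristone vs basal, 4 h 1247. For FCM+mifepristone vs basal, 22 h the count was 2754, for FCM vs cortisol, 4 h 1344 and for FCM vs cortisol, 22 h 3856. The same held for the differences, where the highest other gave 0 too, except for the interaction of FCM and TGFB at 4 h, where it gave 1 and 4 of 4 splits reached the real count. For FCM by TNF, 4 h the count was 20, for FCM by TNF, 22 h 187 and for FCM by TGFB, 4 h 0. For FCM by TGFB, 22 h the count was 125, for cortisol vs basal between times 379 and for FCM vs basal between times 1872. For FCM+mifepristone vs FCM between times the count was 1131, for TNF vs basal between times 727 and for FCM+TNF vs TNF between times 1197. For TGFB vs basal between times the count was 1793 and for FCM+TGFB vs TGFB between times 1206. These fits hold the groups compared alone, so their counts differ from those reported.

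The first pattern weighed was the rise of cytokine and chemokine genes with FCM at 22 h. RNA of fat tissue cells carried over with the medium would bring the abundant transcripts of those cells. Over 8 of them, from adipocytes, macrophages, endothelial cells and lymphocytes, the summed rise was 1.56 ± 6.04 CPM (mean ± SD over 3 lines). The cytokine genes rose by 1570 ± 371 CPM, which argues against RNA carried over from these cell types. The sum sets the fall of CD74 against rises such as that of CD163. RNA of other cells of fat tissue was not covered. Of 56 markers of adipocytes, macrophages, endothelial cells and lymphocytes, 11 had means higher by 1 CPM or more, the largest difference being 11.5 CPM (IL7R). Mean CPM with FCM and in basal medium was for ADIPOQ 0.198 and 0.236, for FABP4 1.39 and 0.158, for CD163 4.72 and 0.547, for CD74 7.14 and 10.3 and for LYZ 0 and 0.160. With the GC trend removed the list's median was 1.65, which argues against GC content. Components of the medium that act without the glucocorticoid receptor are a candidate explanation, since the median was 2.43 with FCM and mifepristone against basal medium. Mifepristone was not given without FCM, so its own share in that median cannot be told apart.

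The second was the fall of proliferation genes with FCM and mifepristone against FCM at 22 h (median -1.73). A glucocorticoid receptor signal that raises these genes by itself would raise them with cortisol, where the median was 0.0207 with an SD of 0.177 over the list. With the GC trend removed the fall was -1.71. An action of mifepristone apart from any glucocorticoid of the medium cannot be told apart from a loss of the receptor's signal. Mifepristone alone was not among the treatments, the data hold no measure of glucocorticoid in the medium, and against basal medium the median was -0.965.

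The last was that the 4 culture pairs with the highest chi-square per degree of freedom all came from line 3. By the SD over genes of the log2 difference between cultures, the ranking was not the same. The pair with FCM and mifepristone at 22 h (0.311) lay below the line 1 pair with cortisol at 4 h (0.365). The pairs with FCM and TGFB at 22 and 4 h (0.427 and 0.374) and with cortisol at 4 h (0.383) lay above it. Of the 8 libraries of the 4 pairs, 0 matched another treatment best and 0 matched another line, which argues against wrong labels. The median size of the correlation across genes between the difference of the cultures and GC content was 0.136, which argues against a GC trend as the whole difference. Over all libraries, 93 of 94 matched their treatment best on 2000 genes and 94 their line. Mitochondrial ribosomal RNA took unlike shares in the 2 cultures of each pair: 5.46 and 8.64% with FCM and TGFB at 22 h, 10.1 and 6.84% with cortisol at 4 h, 9.49 and 11.1% with FCM and TGFB at 4 h, and 6.76 and 8.11% with FCM and mifepristone at 22 h. The first 2 pairs hold 2 of the 3 libraries that stood apart. In the pair of the third, with TGFB at 4 h in line 1 and not among the 4, the shares were 10.8 and 8.78%. A difference in RNA quality or in how these cultures grew was not tested and stays open.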

How the results depend on the processing

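The alternatives without culture pairs that differed most, with the GC trend removed and with the length trend removed were chosen after seeing the data, and all others before the data were examined. The rule for leaving out poor libraries was met by no library, so that alternative gave no values. RLE scaling in place of TMM and removal of the length trend moved none of the 29 counts of genes by over 1.5 times. Of 137 list results past the camera threshold, 63 kept their side of it under every alternative, 70 lost it with an estimated correlation, and none reversed. Of 704 results for single genes, 667 passed, 433 of all kept their direction and side of the threshold under every alternative, and none that passed reversed. The causes of the changes below were not tested, except that leaving out lines or cultures removes samples and that summing libraries or not changes the unit of replication. In simulated data, 27 of 67 genes changed 1.5-fold, 49 of 67 changed 2-fold and 57 of 66 changed 4-fold were called in a comparison of FCM with basal medium at 4 h.

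Without the replicate block, that is without the line term that pairs the samples, every one of the 29 counts of genes was lower by over 1.5 times. Here FCM by TNF and FCM by TGFB stand for the interactions, and between times for a difference between 4 and 22 h. For cortisol vs basal, 4 h the count was 221, for cortisol vs basal, 22 h 365 and for FCM vs basal, 4 h 747. For FCM vs basal, 22 h the count was 1752, for FCM+mifepristone vs FCM, 4 h 993 and for FCM+mifepristone vs FCM, 22 h 697. For TNF vs basal, 4 h the count was 172, for TNF vs basal, 22 h 501 and for FCM+TNF vs TNF, 4 h 558. For FCM+TNF vs TNF, 22 h the count was 1269, for TGFB vs basal, 4 h 94 and for TGFB vs basal, 22 h 2602. For FCM+TGFB vs TGFB, 4 h the count was 702, for FCM+TGFB vs TGFB, 22 h 2175 and for FCM+mifepristone vs basal, 4 h 1087. For FCM+mifepristone vs basal, 22 h the count was 1214, for FCM vs cortisol, 4 h 291 and for FCM vs cortisol, 22 h 1688. For FCM by TNF, 4 h the count was 0, for FCM by TNF, 22 h 14 and for FCM by TGFB, 4 h 0. For FCM by TGFB, 22 h the count was 13, for cortisol vs basal between times 14 and for FCM vs basal between times 473. For FCM+mifepristone vs FCM between times the count was 141, for TNF vs basal between times 11 and for FCM+TNF vs TNF between times 214. For TGFB vs basal between times the count was 248 and for FCM+TGFB vs TGFB between times 535. The culture numbers within a line did not pair samples, with correlations of deviations from -0.144 to 0.125 (median -0.00167), so a block by culture number, given next, pairs by number only.

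With libraries as replicates in place of sums over cultures, and line within time as a block, these counts were over 1.5 times higher. For cortisol vs basal, 4 h the count was 1576, for TNF vs basal, 4 h 1264 and for FCM+TNF vs TNF, 4 h 2588. For TGFB vs basal, 4 h the count was 1208, for FCM vs cortisol, 4 h 2325 and for FCM by TNF, 4 h 67. For FCM by TNF, 22 h the count was 624, for FCM by TGFB, 4 h 46 and for FCM by TGFB, 22 h 1169. For cortisol vs basal between times the count was 701, for TNF vs basal between times 1090 and for FCM+TNF vs TNF between times 2595. For TGFB vs basal between times the count was 3146. With libraries as replicates and a replicate block for each line, time and culture number they were as follows. For cortisol vs basal, 4 h the count was 1525, for TNF vs basal, 4 h 1207 and for TGFB vs basal, 4 h 1135. For FCM vs cortisol, 4 h the count was 2221, for FCM by TNF, 4 h 58 and for FCM by TNF, 22 h 567. For FCM by TGFB, 4 h the count was 32, for FCM by TGFB, 22 h 1080 and for cortisol vs basal between times 656. For TNF vs basal between times the count was 1031 and for FCM+TNF vs TNF between times 2527. With no filter on low counts 7 counts moved. For TGFB vs basal, 4 h the count was 916, for FCM by TNF, 4 h 196 and for FCM by TNF, 22 h 525. For FCM by TGFB, 4 h the count was 126, for FCM by TGFB, 22 h 713 and for cortisol vs basal between times 583. For TNF vs basal between times the count was 717. Fitting each time on its own moved 2. For FCM by TNF, 4 h the count was 2 and for FCM by TGFB, 4 h 0. DESeq2 moved 2. For FCM by TGFB, 4 h the count was 8 and for FCM by TGFB, 22 h 543. Leaving out the culture pairs that differed most moved 2. For FCM vs cortisol, 4 h the count was 877 and for FCM by TGFB, 4 h 8. Removing the GC trend moved 1, FCM by TGFB at 4 h, to 4. For the interaction of FCM and TGFB at 4 h, which had counts of 0 in some of these fits, edgeR gave 2 genes as reported and 886 at an unadjusted p under 0.05, and for that of FCM and TNF at 4 h 6 and 693.

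Leaving out each line, or the first or second culture of each line, gave these ranges of counts. For cortisol vs basal, 4 h the count was from 321 to 1223, for cortisol vs basal, 22 h from 751 to 1904 and for FCM vs basal, 4 h from 1115 to 1375. For FCM vs basal, 22 h the count was from 2428 to 3233, for FCM+mifepristone vs FCM, 4 h from 147 to 3084 and for FCM+mifepristone vs FCM, 22 h from 1350 to 2097. For TNF vs basal, 4 h the count was from 258 to 576, for TNF vs basal, 22 h from 794 to 1459 and for FCM+TNF vs TNF, 4 h from 808 to 1310. For FCM+TNF vs TNF, 22 h the count was from 1939 to 2466, for TGFB vs basal, 4 h from 154 to 422 and for TGFB vs basal, 22 h from 3252 to 3993. For FCM+TGFB vs TGFB, 4 h the count was from 943 to 1566, for FCM+TGFB vs TGFB, 22 h from 2662 to 3498 and for FCM+mifepristone vs basal, 4 h from 232 to 3034. For FCM+mifepristone vs basal, 22 h the count was from 1883 to 2571, for FCM vs cortisol, 4 h from 663 to 1373 and for FCM vs cortisol, 22 h from 2166 to 3172. For FCM by TNF, 4 h the count was from 0 to 6, for FCM by TNF, 22 h from 23 to 122 and for FCM by TGFB, 4 h from 0 to 1. For FCM by TGFB, 22 h the count was from 67 to 271, for cortisol vs basal between times from 58 to 144 and for FCM vs basal between times from 868 to 1570. For FCM+mifepristone vs FCM between times the count was from 37 to 1507, for TNF vs basal between times from 54 to 255 and for FCM+TNF vs TNF between times from 462 to 887. For TGFB vs basal between times the count was from 749 to 1634 and for FCM+TGFB vs TGFB between times from 918 to 1518. Without the first cultures, FCM with mifepristone at 4 h kept 1 sum, whose spread was assumed to be that of the other groups.

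The correlation across genes between responses also moved with no filter on low counts. It was 0.485 for cortisol vs basal and FCM vs basal, 4 h, 0.483 for cortisol vs basal and FCM vs basal, 22 h and -0.0485 for cortisol vs basal and FCM+mifepristone vs FCM, 4 h. Next came -0.0575 for cortisol vs basal and FCM+mifepristone vs FCM, 22 h, -0.431 for TNF vs basal and FCM+TNF vs TNF, 4 h and -0.443 for TNF vs basal and FCM+TNF vs TNF, 22 h. Then came 0.158 for FCM vs basal and FCM+TNF vs TNF, 4 h, 0.160 for FCM vs basal and FCM+TNF vs TNF, 22 h and -0.473 for TGFB vs basal and FCM+TGFB vs TGFB, 4 h. Then came -0.474 for TGFB vs basal and FCM+TGFB vs TGFB, 22 h, 0.148 for FCM vs basal and FCM+TGFB vs TGFB, 4 h and 0.176 for FCM vs basal and FCM+TGFB vs TGFB, 22 h. With libraries not summed, these moved. It was -0.347 for cortisol vs basal and FCM+mifepristone vs FCM, 22 h, -0.141 for TNF vs basal and FCM+TNF vs TNF, 4 h and 0.654 for FCM vs basal and FCM+TNF vs TNF, 4 h. Next came 0.679 for FCM vs basal and FCM+TNF vs TNF, 22 h, -0.375 for TGFB vs basal and FCM+TGFB vs TGFB, 4 h and 0.663 for FCM vs basal and FCM+TGFB vs TGFB, 4 h. Then came 0.677 for FCM vs basal and FCM+TGFB vs TGFB, 22 h. Leaving out lines or cultures gave the ranges that follow. It was 0.50 to 0.56 for the correlation of responses, cortisol vs basal and FCM vs basal, 4 h, 0.42 to 0.49 for the correlation of responses, cortisol vs basal and FCM vs basal, 22 h and -0.50 to -0.34 for the correlation of responses, FCM vs basal and FCM+mifepristone vs FCM, 4 h. Next came -0.52 to -0.48 for the correlation of responses, FCM vs basal and FCM+mifepristone vs FCM, 22 h, -0.22 to -0.13 for the correlation of responses, cortisol vs basal and FCM+mifepristone vs FCM, 4 h and -0.31 to -0.18 for the correlation of responses, cortisol vs basal and FCM+mifepristone vs FCM, 22 h. Then came -0.31 to -0.19 for the correlation of responses, TNF vs basal and FCM+TNF vs TNF, 4 h, -0.31 to -0.24 for the correlation of responses, TNF vs basal and FCM+TNF vs TNF, 22 h and 0.45 to 0.54 for the correlation of responses, FCM vs basal and FCM+TNF vs TNF, 4 h. Then came 0.48 to 0.56 for the correlation of responses, FCM vs basal and FCM+TNF vs TNF, 22 h, -0.46 to -0.39 for the correlation of responses, TGFB vs basal and FCM+TGFB vs TGFB, 4 h and -0.45 to -0.40 for the correlation of responses, TGFB vs basal and FCM+TGFB vs TGFB, 22 h. Then came 0.42 to 0.54 for the correlation of responses, FCM vs basal and FCM+TGFB vs TGFB, 4 h and 0.48 to 0.57 for the correlation of responses, FCM vs basal and FCM+TGFB vs TGFB, 22 h.

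The sign of some differences that did not pass the test changed. MMP3: FCM+TNF vs TNF, 22 h stood at -0.20 as reported and from -0.80 to 0.26 with lines or cultures left out, changing sign without line 1. ZBTB16: FCM+mifepristone vs basal, 22 h stood at 0.83 as reported and from -0.7054 to 1.667 with lines or cultures left out, changing sign without the second cultures. TSC22D3: genes whose response differs between times, cortisol vs basal stood at 0.00321 as reported and from -0.21 to 0.14 with lines or cultures left out, changing sign without line 2 and without the second cultures. It changed sign too, at -0.00198 with DESeq2 and -0.00255 with the length trend removed. ZBTB16: genes whose response differs between times, cortisol vs basal stood at -0.0106 as reported and from -2.06 to 1.66 with lines or cultures left out, changing sign without line 2 and without the first cultures. It changed sign too, at 0.0154 with no filter, 0.0385 without the line term, 0.11 with libraries not summed, 0.10 with libraries not summed and a culture number block, 0.00317 with DESeq2 and 0.0432 with the GC trend removed. FKBP5: genes whose response differs between times, FCM vs basal stood at -0.16 as reported and from -0.41 to 0.33 with lines or cultures left out, changing sign without line 2. ZBTB16: genes whose response differs between times, FCM vs basal stood at -0.67 as reported and from -2.98 to 1.32 with lines or cultures left out, changing sign without line 2 and without the first cultures. FKBP5: genes whose response differs between times, FCM+mifepristone vs FCM stood at 0.52 as reported and from -0.0441 to 1.19 with lines or cultures left out, changing sign without line 2. TSC22D3: genes whose response differs between times, FCM+mifepristone vs FCM stood at 0.34 as reported and from -0.0521 to 0.69 with lines or cultures left out, changing sign without line 1 and without the first cultures. IL6: genes whose response differs between times, FCM+TNF vs TNF stood at -0.22 as reported and from -0.60 to 0.0661 with lines or cultures left out, changing sign without the first cultures. PMEPA1: genes whose response differs between times, FCM+TGFB vs TGFB stood at -0.11 as reported and from -0.34 to 0.0939 with lines or cultures left out, changing sign without line 2.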

Other observations

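The tests in this part were planned, apart from the gene lists set against cortisol, which were chosen after the results were seen. Set against cortisol at 22 h, FCM gave higher values for proliferation genes, where 23 of 26 were higher and 0 lower (25 and 0 adjusted over the list alone), for immediate early genes, where 15 of 22 were higher and 2 lower (15 and 2 adjusted over the list alone), and for matrix-degrading enzymes, where 8 of 17 were higher and 0 lower (9 and 0 adjusted over the list alone). Contractile genes went the other way: 0 of 16 were higher and 12 lower (0 and 13 adjusted over the list alone). Of the glucocorticoid receptor targets 9 of 26 were higher and 6 lower (10 and 9 adjusted over the list alone). These lists were counted without a camera test.

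Several lists moved in ways not described so far. With TGFB at 22 h, of the hypoxia and glycolysis genes 14 of 26 rose and 3 fell (17 and 3 adjusted over the list alone), with adjusted p = 0.00210 and adjusted p = 0.151 with an estimated correlation, and of the cholesterol and fatty acid synthesis genes 10 of 27 rose and 4 fell (13 and 4 adjusted over the list alone), with adjusted p = 6.10e-04 and adjusted p = 0.0997 with an estimated correlation. With cortisol at 22 h, of the hypoxia and glycolysis genes 2 of 26 rose and 9 fell (2 and 12 adjusted over the list alone), with adjusted p = 1.11e-04 and adjusted p = 0.0666 with an estimated correlation. Immediate early genes, which encode transcription factors switched on without new protein synthesis, were followed with FCM added to TNF, where 10 of 22 rose and 3 fell (11 and 3 adjusted over the list alone), with adjusted p = 0.00108 and adjusted p = 0.0307 with an estimated correlation at 22 h. With FCM added to TGFB, 11 of 22 rose and 2 fell (12 and 2 adjusted over the list alone), with adjusted p = 0.00105 and adjusted p = 0.0314 with an estimated correlation. Of the sublining markers with FCM at 22 h, 2 of 17 rose and 7 fell (3 and 8 adjusted over the list alone), with adjusted p = 0.0229 and adjusted p = 0.215 with an estimated correlation. The lymphocyte marker list, of 12 genes, had fewer than 5 measured members and was not tested.

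Of genes changed by TNF at 22 h, 424 rose and then fell with FCM added and 133 rose further, against 114 and 115.5 for independent lists. Of those that TNF lowered, 169 rose with FCM and 159 fell further (88.7 and 87.5). With the shared cultures split, these counts were 351 and 116, and 114 and 134. For TGFB, 822 genes rose and then fell and 213 rose further (287 and 321 for independent lists), while 656 fell and then rose and 201 fell further (328 and 292). With the shared cultures split, they were 616 and 213, and 495 and 196. These comparisons share the cytokine cultures: the correlations across genes were -0.228 and -0.391 (-0.443 for TNF with no filter on low counts), simulated unchanged groups gave -0.507 and -0.527, and with the shared cultures split they were -0.0770 and -0.198. The covariance differed from the simulated one by -0.0220 and -0.203.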
